A study of Mus musculus with 21 samples.

How the data were processed

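The series measured messenger RNA by bulk RNA sequencing in choroid plexus and hypothalamus of wild-type C57BL/6J mice in which Ins2, a mouse insulin gene, was overexpressed in the choroid plexus, and in control mice listed as untreated. The choroid plexus is the epithelial tissue of the brain ventricles that secretes cerebrospinal fluid. Choroid plexus gave 6 Ins2 and 5 control samples, and hypothalamus gave 5 Ins2 and 5 control samples, 21 in all. The labels do not state how Ins2 was introduced. The hypothalamus control columns carry a GFP prefix in the deposited table, while the labels call the same samples untreated, so whether those animals received a GFP vector is not settled here. Nothing in the labels says that replicates came from separate animals, so p-values measure the spread between these samples.

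RNA was isolated with a PicoPure kit, and poly(A) RNA was made into strand-marked (dUTP) libraries, per the labels' protocols. Alignment used HISAT2, gene counting featureCounts and scaling DESeq2, with the mouse build GRCm38 (mm10), per the submitters' processing notes. Their versions and the strand setting of the counting are not given in the sources used here. Because that strand setting is unknown, a gene that overlaps another gene on the opposite strand is read as uncertain. Of 133 gene symbols of the report and the closing section that were checked, 59 overlapped such a gene and 40 shared exon bases with it. The report notes this for some of them only. The largest shares of exon bases were those of C1ql3 (64.2%), Gbx2 (43.5%), Pcdhgc3 (28.4%), Tapbp (24.9%) and Timp3 (21.3%). The deposited signal values are gene counts divided by the authors' DESeq2 size factors, per the labels, with 1 table per tissue that was scaled on its own. Levels were therefore never compared between the tissues, and only fold changes were.

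Each table held 25239 gene symbols, of which 5641 in choroid plexus and 4487 in hypothalamus were 0 in every library. The low values of each library were whole multiples of 1 step, and dividing by it gave whole reads, within 0.02, for 100% of values in every library. Reads per library, recovered in this way, ran from 25.95 to 36.3 M (M, 1e+06) in choroid plexus and from 27.4 to 62.1 M in hypothalamus. At these depths a count of 0 allows up to 3 reads, or 0.0483 to 0.116 reads per M reads. That limit covers counting error only. Within each group no pair of libraries was alike enough to be 1 library deposited 2 times: the lowest chi-square per gene was 7.05 (choroid plexus controls 3 and 4) and 5.55 (hypothalamus Ins2 replicates 3 and 4). Reads of the Y-linked gene Ddx3y were 2781 to 6828 per library and those of Xist, which is expressed from the inactive X chromosome, were at most 97.

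The main test was limma (version 3.58.1, R 4.3.3) with lmFit and eBayes with a mean-variance trend on log2(value + 1), within each tissue, with no covariate. Genes with a mean value of at least 10 were tested, 14533 in choroid plexus and 16363 in hypothalamus. P-values were two-sided and adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are on the log2(value + 1) scale and understate those of low genes. Intervals are at 95% confidence. The median standard error of a log2 fold change was 0.10 in choroid plexus and 0.08 in hypothalamus. Single genes also had an exact two-sided permutation test over all 462 splits of the choroid plexus libraries or 252 splits of the hypothalamus libraries, whose smallest possible p-values are 0.00216 and 0.00794.

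Gene lists, 53 in all, covered cell types, pathways and peptides of both tissues and were tested with limma's camera with a preset correlation of 0.01 where at least 5 members were tested. Camera with an estimated correlation and fry were run as alternatives, as was an exact permutation test of each list's score, the mean log2(value + 1) of its members in a library. In choroid plexus 991 of 1018 members were in the table, 22 of them under another symbol, and in hypothalamus 1158 of 1185, 23 of them under another symbol. Lists of neutrophils, red blood cells and mitochondrial transcripts in both tissues, of B and plasma cells in choroid plexus and of sex-linked genes in hypothalamus had too few tested members. The difference between the tissues was tested per gene as the difference of the log2 fold changes, with both moderated errors and Welch-Satterthwaite degrees of freedom, and per list by 100000 permutations of the library labels within each tissue. Both tests treat the choroid plexus and hypothalamus libraries as independent, which need not hold if the tissues came from the same animals.

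The design, the lists, the gene naming rule and most alternatives were fixed before the data were examined. The rule named Ins2 and Ins1, a fixed set of genes (Ttr, Insr, Irs2 and Kl in choroid plexus; Agrp, Npy, Pomc, Cartpt, Insr, Lepr and Ttr in hypothalamus), the largest changes past the threshold or, where fewer than 5 passed in a direction, the 5 smallest unadjusted p-values, and up to 3 members with the highest mean of each described list. Predicted genes with Gm or Rik names were counted and not named. Some genes that the rule would name are not reported here. List members that passed adjustment over their list alone, glial genes given per library, plasma cell genes and the genes that differed between tissues were named after their values were seen. The same holds for Slfn1, Sim1, Otp and Corin.

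Alternatives were other pseudocounts (0.5 and 5), other filters (none and a mean of 50), scaling to equal totals or upper quartiles, array weights, robust eBayes, a minimum absolute log2 fold change of 1, edgeR (4.0.16) quasi-likelihood tests and DESeq2 (1.42.0) on the recovered reads, blocks by replicate number, and leaving out each library in turn. Added after seeing the data were the removal of choroid plexus controls 2 and 5 together, removal of each library's GC or length trend in 20 bins, and the macrophage list score as a covariate. GC content and length came from the longest GENCODE M21 transcript of each gene, available for 98.2% of tested genes in choroid plexus and 98.1% in hypothalamus, and trends were measured on genes with a mean above 100. Gene positions are GENCODE M21 positions on GRCm38.

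The tests were tested on simulated data with 200 changed genes per tissue. In simulated choroid plexus data of 14492 genes, limma recovered 32% of genes changed 1.25-fold, 55.1% at 1.5-fold, 82.6% at 2-fold and 95.7% at 4-fold, with 6 false among 131 calls. In simulated hypothalamus data of 16353 genes it recovered 48%, 70%, 79.6% and 100%, with 12 false among 160 calls. The simulated tissue difference over 13952 genes recovered 224 of 353 differing genes with 15 false calls, and of 40 simulated lists camera called the shifted one and 0 others in each tissue. Simulated counts were drawn gene by gene and the lists at random, so their members were not correlated. The estimated correlation of real lists reached 0.74, so the simulation does not test camera's preset correlation. The recovery rates hold for data with 200 changed genes and may be lower where few genes change. Figures were drawn with matplotlib 3.10.9.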

Results

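RNA sequencing was used to measure how overexpression of the insulin gene Ins2 in the choroid plexus altered transcripts of that tissue and of the hypothalamus, which holds the arcuate nucleus named in the study's title. In choroid plexus the 6 Ins2 libraries held 32.2, 36.3, 27.2, 25.95, 31.0 and 27.5 M reads in genes (M, 1e+06) and the 5 control libraries 28.7, 34.9, 27.75, 29.9 and 27.6 M. In hypothalamus the 5 Ins2 libraries held 33.6, 62.1, 36.2, 31.1 and 34.3 M and the 5 control libraries, replicates 1 to 4 and 6, held 47.2, 30.9, 35.9, 27.6 and 27.4 M. Mean depth did not separate the groups in choroid plexus (30.03 against 29.8 M reads; exact permutation p = 0.903) or hypothalamus (39.5 against 33.8 M reads; exact permutation p = 0.476).

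The first comparison asked whether the Ins2 transcript was raised in the choroid plexus. Ins2 (GRCm38 chromosome 7, 142678656 to 142743381, minus strand) rose from 430 ± 50.7 size-factor-scaled reads in control choroid plexus (SD, n = 5) to 826 ± 162 in Ins2 choroid plexus (n = 6), a fold of 1.90 (95% interval 1.59 to 2.27; limma adjusted p = 0.00594). Every Ins2 library, at 598 to 1041, lay above every control library, at 387 to 501 (exact permutation p = 0.00433). Control libraries held 13.1 to 16.8 Ins2 reads per M reads, so Ins2 was also measured without overexpression. Reads of an introduced Ins2 sequence and of the native gene cannot be separated in these values. The second mouse insulin gene, Ins1 (chromosome 19, 52264297 to 52265476), had 0 reads in each of the 21 libraries.

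In hypothalamus Ins2 was near the limit of detection. It had 0 reads in 9 of 10 libraries, which allows up to 0.0483 to 0.11 reads per M reads, and 5 reads in Ins2 replicate 4 (exact permutation p = 1). Ttr, the transthyretin gene that took 10.7% to 12.98% of reads in choroid plexus, had 0 to 48 reads per hypothalamus library, with 15.6 ± 14.4 in controls and 15.3 ± 6.95 in Ins2 hypothalamus (limma adjusted p = 0.798).

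**Figure D1:**
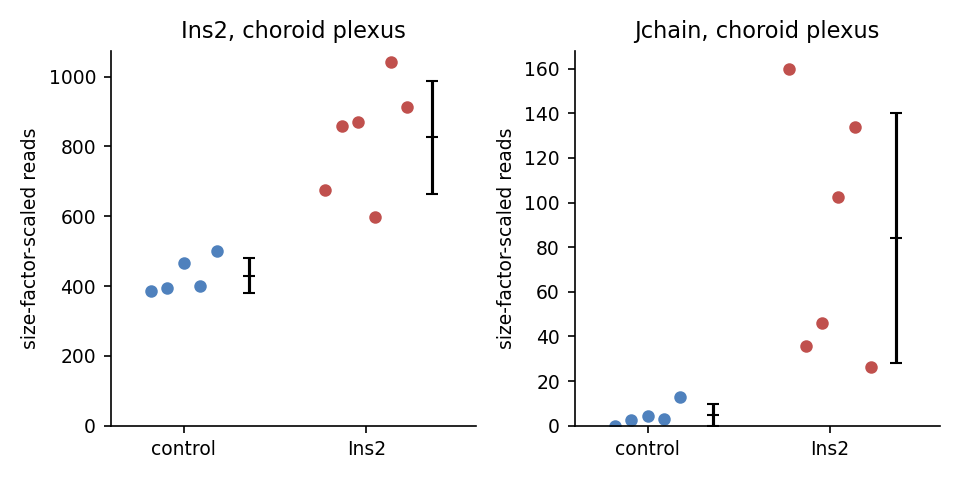
Size-factor-scaled reads of Ins2 (left) and Jchain (right) in each choroid plexus library, control in blue and Ins2 in red, with the mean and SD of each group as black bars beside the points. Ins2 libraries sit between 598 and 1041 for Ins2 and between 26.3 and 160 for Jchain, above all controls for both genes.

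Across the choroid plexus transcriptome 2 genes passed the test, both higher: Ins2 and Jchain, which encodes the joining chain of polymeric immunoglobulins. Jchain (chromosome 5, 88519809 to 88527891) rose from 4.57 ± 4.94 in controls (n = 5) to 84.0 ± 56.1 in Ins2 choroid plexus (n = 6), a fold of 17.1 (95% interval 7.12 to 40.9; limma adjusted p = 0.0131; exact permutation p = 0.00216, the smallest possible). Among the 14533 genes tested, 903 had an unadjusted p under 0.05 (369 higher, 534 lower), where chance gives 727, and 89 (0.612%) had ranges that did not overlap, where chance gives 0.433%. As genes are correlated across libraries, such counts can lie far from the chance value, and they were not set against other splits. No gene was lower at the adjusted threshold in this fit or by edgeR. Limma with array weights called 6 genes, 2 higher and 4 lower, and DESeq2 on the recovered reads called 25 genes, 4 higher and 21 lower. The call of Jchain was lost without Ins2 replicate 1 (log2 fold change 3.85, adjusted p = 0.0788), Ins2 replicate 4 (3.975, 0.0798) or control 4 (4.09, 0.0572), and DESeq2 gave it no adjusted p. As its control values were low, the log2 fold change of 4.09 was 3.08 with a pseudocount of 5 and 4.40 with 0.5, called in both cases. The call of Ins2 held without each library in turn.

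The smallest unadjusted p-values below the threshold belonged to genes with small differences. Map1a, a microtubule-associated protein, was at 2150 ± 195 in controls and 1675 ± 83.2 in Ins2 choroid plexus, a fold of 0.781 (limma adjusted p = 0.09996). Fat1, an atypical cadherin, was at 9157 ± 620 and 7516 ± 443, a fold of 0.821 (adjusted p = 0.190). The other 3 genes lowest by this rule were Nfatc2, a calcium-regulated transcription factor (fold 0.782, adjusted p = 0.190), Fbxl20 (fold 0.848, adjusted p = 0.277) and Amot (fold 0.817, adjusted p = 0.385). On the higher side stood the imprinted long noncoding RNA Kcnq1ot1 (853 ± 110 and 1280 ± 256, fold 1.49, adjusted p = 0.274), the noncoding RNA Dancr (73.5 ± 13.2 and 125 ± 24.5, fold 1.69, adjusted p = 0.385) and Wdr78, of the dynein of motile cilia (fold 1.18, adjusted p = 0.385). Kcnq1ot1, Map1a, Fat1, Wdr78 and Dancr each overlap a gene on the opposite strand (Kcnq1, Ppip5k1 and Mier1 among them). Without Ins2 replicate 5, Kcnq1ot1 (log2 fold change 0.65) and the MHC class I transactivator gene Nlrc5 (0.92) passed with limma (adjusted p = 0.046 each). DESeq2 called 7 of these 8 genes, all but Dancr, and limma with array weights called Map1a, Fat1, Nfatc2 and Fbxl20.

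Transcripts that identify the choroid plexus epithelium differed little between the groups. Ttr was at 3458000 ± 152300 in controls and 3511000 ± 264900 in Ins2 choroid plexus (fold 1.01; limma adjusted p = 0.989). Kl, the klotho gene, was at 140000 ± 6563 and 129400 ± 8687 (fold 0.923; adjusted p = 0.824). The insulin receptor gene Insr was at 3736 ± 304 and 3300 ± 398 (fold 0.88, 95% interval 0.790 to 0.981; adjusted p = 0.729). It overlaps transcripts of the opposite strand but shares 0 exon bases with them. Irs2, an insulin receptor substrate, was at 2369 ± 272 and 2431 ± 364 (fold 1.02; adjusted p = 0.977), and 2.56% of its exon bases overlap a gene on the opposite strand. As a list, 32 epithelial genes had a median log2 fold change of -0.06, with 23 of 32 below 0 (camera adjusted p = 0.00302; adjusted p = 0.538 with an estimated correlation). The 23 genes of ion transport, among them Slc4a2 (fold 0.959) and Clic6 (0.969), also had -0.06 (camera adjusted p = 0.00413; adjusted p = 0.538 with an estimated correlation). No member of either list passed adjusted over the list alone. The ion transport call was lost without Ins2 replicate 4 (median -0.05, adjusted p = 0.0692), and the epithelial one without controls 2 and 5 together (median -0.06, adjusted p = 0.0518), which leaves fewer samples. With equal totals per library both medians were -0.04.

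Of 38 gene lists tested in choroid plexus, camera called 14, 7 upward and 7 downward. 0 were called with an estimated correlation (smallest adjusted p = 0.538, with 1 unadjusted p under 0.05) and 0 by fry. An exact permutation test of list scores per library gave 0 adjusted calls and 3 lists with an unadjusted p under 0.05, those of T and NK cells (0.0281), insulin signalling (0.0433) and ion transport (0.0455). The 24 uncalled lists had camera adjusted p-values from 0.0639 (cholesterol synthesis) to 0.898 (cell cycle). They included neurons (median log2 fold change 0.15, adjusted p = 0.249), endothelium (-0.10, 0.320) and FOXO and insulin-repressed genes (-0.07, 0.318). Some of these lists passed when 1 library was left out. The neuron median was 0.31 (adjusted p = 0.0101) without control 2 and 0.27 (0.0111) without Ins2 replicate 2. That of endothelium was -0.23 (0.00189) without control 5, -0.20 (0.0233) without Ins2 replicate 5 and -0.27 (1.789e-04) with the macrophage score as a covariate. That of cholesterol synthesis was -0.18 (2.25e-10) without control 5. Adjusted over the list alone, the neurofilament gene Nefh of the neuron list (log2 fold change 0.35) and Six3 of the striatum list (0.21) passed.

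Among called lists, immune ones had the largest upward medians. In Ins2 replicates 4 and 5, however, the scores of MHC class I (-0.12 and -0.004) and interferon-stimulated genes (-0.08 and -0.12) were below the control mean. Exact permutation p-values of the scores were 0.0779 (MHC class I), 0.0952 (interferon) and 0.106 (MHC class II). Chemokine and inflammation genes were not called (median 0.03, camera adjusted p = 0.108), but passed without control 2 or Ins2 replicates 4 or 5. Of 19 tested MHC class I genes, which present intracellular peptides, 17 were above 0, with a median log2 fold change of 0.21 (camera adjusted p = 4.41e-07; adjusted p = 0.538 with an estimated correlation). Among them Tapbp was at 5382 ± 271 and 5478 ± 412 (fold 1.02), H2-K1 went from 3074 ± 275 to 3772 ± 493 (fold 1.22), B2m from 3539 ± 278 to 4320 ± 764 (fold 1.21) and Nlrc5, the transactivator of class I genes, from 168 ± 23.9 to 296 ± 89.1 (fold 1.69). Nlrc5 overlaps a gene on the opposite strand over 0.918% of its exon bases. Adjusted over the list alone H2-K1 (0.0251) and Nlrc5 (0.0157) passed, and over all genes tested none did. H2 genes are paralogs that can share reads. Of 40 interferon-stimulated genes 36 were above 0 (median 0.25, camera adjusted p = 2.14e-06; adjusted p = 0.538 with an estimated correlation). Among them were Bst2 at a fold of 1.096 and Ifih1 at 1.06, and 0 members passed adjusted over the list alone. The list median was 0.16 (camera adjusted p = 2.11e-04) without control 1.

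The MHC class II list, 9 genes of antigen-presenting cells, had a median log2 fold change of 0.71 (camera adjusted p = 0.0019; adjusted p = 0.538 with an estimated correlation). Cd74 was at 1282 ± 634 in controls and 2295 ± 809 in Ins2 choroid plexus (fold 1.91, 95% interval 1.24 to 2.94) and H2-Aa at 440 ± 194 and 768 ± 255 (fold 1.84). Both passed adjusted over the list alone (0.0286 each). H2-Eb1 stood at a fold of 1.68 and H2-Ab1 at 1.64. Control 5 had the lowest Cd74, 439 against 1043 to 3271 in the other libraries, and without it the list median was 0.29 (adjusted p = 0.0242). Without controls 2 and 5 it was 0.21 (0.118). Of 27 genes in the T and NK cell list 7 were tested, 5 above 0 and 2 below 0. Their median was 0.91 (camera adjusted p = 0.00353; adjusted p = 0.538 with an estimated correlation). That median was the value of Thy1, a gene with few reads here. Thy1 was at 23.03 ± 16.27 in controls and 39.84 ± 20.18 in Ins2 choroid plexus (exact permutation p = 0.154). Adjusted over the list alone Cd8a (6.01 ± 6.72 and 32.2 ± 22.2, fold 5.64) and the chemokine receptor gene Cxcr6 (12.4 ± 3.26 and 31.6 ± 9.26, fold 2.39) passed, both 0.00773. That list was not called without Ins2 replicate 6 (median 0.44, adjusted p = 0.0734) and had a median of 0.55 without control 4. Macrophage and microglia genes (29 tested, among them Apoe at a fold of 0.946 and Cd9 at 1.003) had a median of 0.30 (camera adjusted p = 1.81e-04; adjusted p = 0.645 with an estimated correlation). It was 0.09 (0.238) without control 5, 0.17 (0.0196) without Ins2 replicate 1, and 0.11 (0.118) without controls 2 and 5 together.

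**Figure D2:**
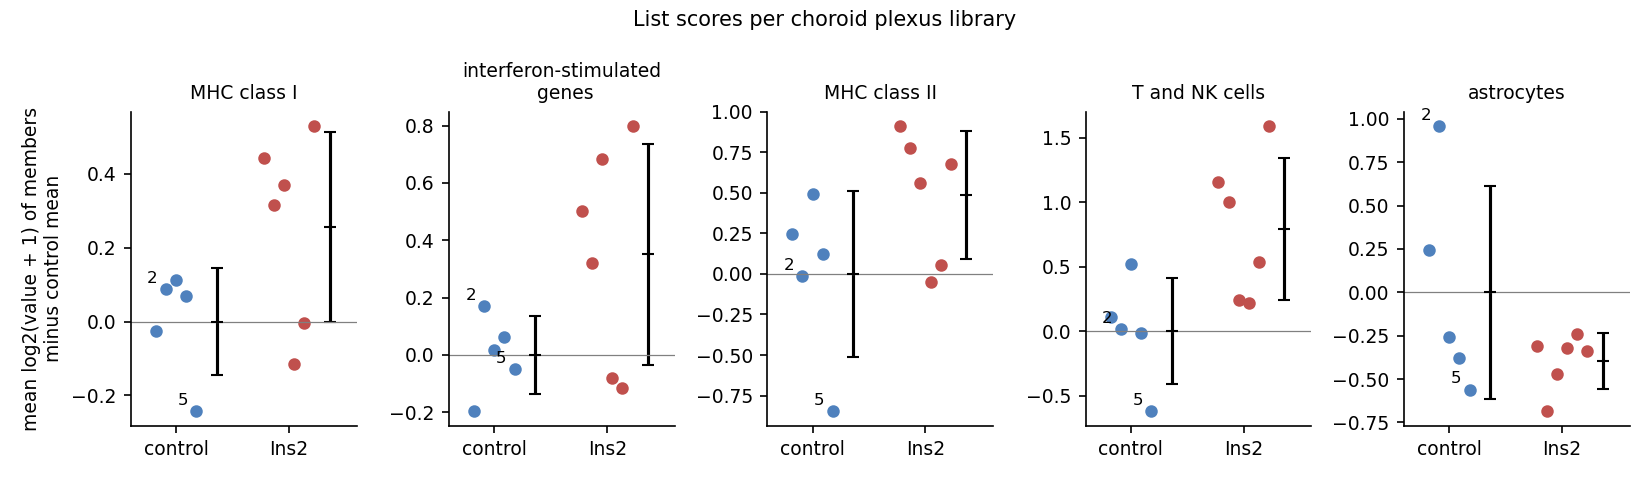
Score of 5 gene lists in each choroid plexus library, the mean log2(value + 1) of the members minus the control mean, with group mean and SD as black bars. Controls 2 and 5 are numbered. MHC class I scores of the Ins2 libraries run from -0.12 to 0.53 and overlap those of the controls, from -0.24 to 0.11, and control 2 stands at 0.96 for astrocytes.

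Genes of brain tissue next to the plexus set control 2 apart. Of 20 astrocyte genes 19 were below 0 in the Ins2 group (median log2 fold change -0.31, camera adjusted p = 4.17e-05; adjusted p = 0.538 with an estimated correlation), and 0 passed adjusted over the list alone. The 3 highest members, Ndrg2, Glul and Slc7a10, had folds of 0.988, 1.04 and 0.974. In control 2 the astrocyte gene Gfap reached 4507, against 89.6 to 453 in the other 10 libraries, and Aqp4 848 against 75.2 to 238. The myelin gene Mbp reached 25150 against 1471 to 3333. Without control 2 the astrocyte median was -0.10 (adjusted p = 0.0229). It was -0.20 without control 1, -0.49 without control 5 and -0.19 without Ins2 replicate 2. It was -0.17 with a mean of at least 50 and -0.53 with the macrophage score as a covariate. Oligodendrocyte and myelin genes were not called (median -0.21, adjusted p = 0.114), and the list moved with single libraries. Without control 2 the direction turned (median 0.28, adjusted p = 0.00509). The list was called downward without controls 1, 3, 4 or 5 (medians -0.36, -0.41, -0.52 and -0.59, adjusted p = 0.00313 to 0.0463) or Ins2 replicate 5 (-0.31, 0.0358). It was also called downward with the macrophage score as a covariate (-0.52, 0.0059), a pseudocount of 5 (-0.34, 0.0384) or equal totals per library (-0.19, 0.0296). All 10 tested genes of peptide hormone processing and beta cells were below 0 (median -0.24, camera adjusted p = 0.00337; adjusted p = 0.538 with an estimated correlation). Furin, Cpe and Scg5 stood at folds of 0.95, 0.929 and 0.936. This call was lost without control 2 (median -0.11, adjusted p = 0.0852), and the median was -0.09 without Ins2 replicate 2, -0.41 without control 3 and -0.35 without Ins2 replicate 5. It was -0.12 (adjusted p = 0.0591) without controls 2 and 5 together, -0.09 with a mean of at least 50 and -0.38 with the macrophage score as a covariate.

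**Figure D3:**
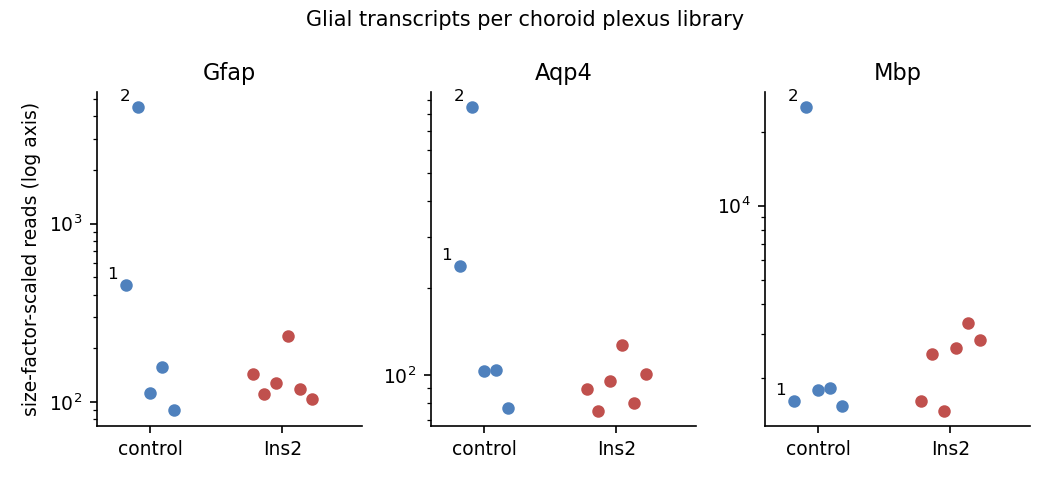
Size-factor-scaled reads of the astrocyte genes Gfap and Aqp4 and the myelin gene Mbp in each choroid plexus library on log axes, control in blue and Ins2 in red, with controls 1 and 2 numbered. Control 2 is the highest library for all 3 genes, at 4507, 848 and 25150.

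Lists of insulin action and growth factors moved by small amounts in choroid plexus. The 12 genes of the IGF system had a median log2 fold change of -0.11 (camera adjusted p = 0.00337; adjusted p = 0.538 with an estimated correlation). The growth factor gene Igf2 was at 144100 ± 6358 and 135000 ± 6691 (fold 0.937), with Igfbp2 at a fold of 0.936 and the receptor gene Igf2r, which passed adjusted over the list alone (0.0319), at 0.871. The median was -0.06 (0.105) without Ins2 replicate 4, -0.19 without control 5 and -0.20 with the macrophage score as a covariate. Of 36 insulin signalling genes 21 were below 0 (median -0.03, camera adjusted p = 0.0428; adjusted p = 0.538 with an estimated correlation), with Igf1r and Akt2 at folds of 0.922 and 0.986. Extracellular matrix genes (35 tested, median -0.10, camera adjusted p = 0.0132; adjusted p = 0.66 with an estimated correlation) included Col9a3, Timp3 and Col8a1 at folds of 1.004, 0.948 and 0.922 and Col8a2 at 0.867, which passed adjusted over the list alone (0.0223). The circadian clock list (18 genes, median 0.07, camera adjusted p = 0.0299; adjusted p = 0.538 with an estimated correlation) held Tef, Clock and Nr1d2 at folds of 1.06, 0.959 and 1 and the clock repressor gene Per2 at 1004 ± 113 and 1364 ± 257 (fold 1.35), which passed adjusted over the list alone (0.0148). Heat shock genes (18 tested, median 0.03, camera adjusted p = 0.0461; adjusted p = 0.645 with an estimated correlation) had Hspa8, Hsp90ab1 and Hsp90aa1 at folds of 1.03, 1.005 and 1.03.

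The calls of those last 4 lists were lost when any of several single libraries was left out, which also leaves fewer samples. The insulin signalling call was lost without Ins2 replicates 1, 3 or 5 or controls 1 or 5 (medians -0.04, -0.03, -0.01, -0.04 and -0.02, adjusted p = 0.0506 to 0.238), and with equal totals per library (median -0.004, adjusted p = 0.088). It was also lost with a mean of at least 50 (-0.03, 0.0569), the length trend of each library removed (-0.007, 0.506), the macrophage score as a covariate (-0.03, 0.362) or without controls 2 and 5 together (-0.02, 0.322). The extracellular matrix call was lost without Ins2 replicates 2, 4 or 6 or controls 1 or 3 (medians -0.06, -0.04, -0.06, -0.04 and -0.07, adjusted p = 0.0753 to 0.304), with a median of -0.18 without control 5. The circadian call was lost without Ins2 replicates 2 or 4 or controls 2 or 5 (medians 0.07, 0.06, 0.07 and 0.02, adjusted p = 0.0556 to 0.166). Without controls 2 and 5 together the circadian median turned to -0.02 (adjusted p = 0.669), and those of the IGF system, extracellular matrix and heat shock lists were -0.19, -0.18 and 0.09. The heat shock call was lost without Ins2 replicates 2 or 5 or controls 1, 3 or 4 (medians 0.02, 0.02, 0.02, 0.02 and 0.03, adjusted p = 0.0832 to 0.273), with a median of 0.09 without control 2. Without Ins2 replicate 4 the insulin signalling median was -0.04 and the heat shock median 0.05. With the length trend of each library removed the extracellular matrix call (median -0.06, adjusted p = 0.0502) and the heat shock call (0.02, 0.128) were lost. The heat shock median was 0.05 with equal totals per library, and that of extracellular matrix -0.22 with the macrophage score as a covariate.

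The hypothalamus comparison asked whether insulin made in the choroid plexus altered transcripts at a distance. No gene passed among 16363 tested with limma (smallest adjusted p = 0.309), while 1624 had an unadjusted p under 0.05 (957 higher, 667 lower), where chance gives 818, and 245 (1.497%) had ranges that did not overlap, where chance gives 0.794%. Genes are correlated across libraries, so such counts can lie far from the chance value without a response. These counts were not set against other splits, and the fold changes went with GC content (Spearman rho 0.37). Both edgeR fits called 0 genes, and DESeq2 called 39, 30 higher and 9 lower, of which 38 changed less than 1.5-fold. On the higher side the smallest unadjusted p-values belonged to Rn45s, the ribosomal RNA precursor, at 67860 ± 7778 in controls and 109000 ± 29120 in Ins2 hypothalamus (n = 5 each, fold 1.57, limma adjusted p = 0.309), and to Il17rc, an interleukin-17 receptor subunit gene, at 242 ± 25.9 and 358 ± 20.4 (fold 1.48). They were followed by Zdhhc14 (fold 1.27), Kirrel3 (1.19) and the neural transcription factor gene Pou3f3 (1.24). On the lower side they belonged to Lpcat2 (610 ± 35.4 and 468 ± 33.6, fold 0.766), Pnp2 (122 ± 9.74 and 65.7 ± 16.6, fold 0.53), Srp54a (0.868), Luc7l3 (0.881) and the kappa opioid receptor gene Oprk1 (1068 ± 67.6 and 871 ± 59.5, fold 0.816), all with a limma adjusted p of 0.309. Pnp2 overlaps its paralog Pnp and Srp54a has near-identical copies, so their values are uncertain. Kirrel3 overlaps a transcript of the opposite strand but shares 0 exon bases with it. Rn45s was at 150600 and 128900 in Ins2 replicates 1 and 2 and at 88140 to 89050 in replicates 3 to 5. The libraries were made from poly(A) RNA, so its level is also read as uncertain. Without control 6, 18 genes were called, Rn45s (log2 fold change 0.66) among them, and without control 4, Rn45s alone (0.70, adjusted p = 0.0277). Of the genes named above, DESeq2 called Rn45s, Kirrel3, Pou3f3, Srp54a and Luc7l3. Limma with the block by title number called Rn45s and Pou3f3 (adjusted p = 0.0134 and 0.0263), and with the block by bracketed code Rn45s (0.00179).

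Insulin- and leptin-pathway genes of the hypothalamus did not pass over all genes tested. Insr stood at a fold of 0.94 (limma adjusted p = 0.665), the leptin receptor gene Lepr was at 106 ± 4.47 and 118 ± 31.1 (fold 1.07; adjusted p = 0.886), and Irs2 was at 3582 ± 491 and 4373 ± 219 (fold 1.23, 95% interval 1.11 to 1.36; adjusted p = 0.309). Irs2, named here after its values were seen, passed adjusted over the list alone in the lists of FOXO and insulin-repressed genes (0.00867) and of insulin signalling, and over all genes by DESeq2 and by limma without control 6 (log2 fold change 0.36, adjusted p = 0.0459).

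The peptides of feeding circuits were compared because the study's title concerns feeding and the arcuate nucleus. None of 25 tested genes of the feeding peptide lists passed with limma, either over all genes or adjusted over the list alone. Of them 2 had an unadjusted p under 0.05, and 17 had a log2 fold change below 0. The 17 include the transcription factor genes Sim1 and Otp and the protease gene Corin, which do not encode feeding peptides (-0.16, -0.05 and -0.12). The appetite-promoting arcuate peptide genes Agrp (chromosome 8, 105566698 to 105637393) and Npy (chromosome 6, 49822710 to 49829507) were at 353 ± 93.4 and 288 ± 34.0 (fold 0.835, 95% interval 0.669 to 1.04; exact permutation p = 0.23) and at 896 ± 175 and 802 ± 108 (fold 0.902, 0.762 to 1.07; exact permutation p = 0.381). The appetite-suppressing ones, Pomc (chromosome 12, 3954951 to 3960642) and Cartpt (chromosome 13, 99898489 to 99901091), were at 2907 ± 347 and 2626 ± 279 (fold 0.905, 0.807 to 1.01; exact permutation p = 0.214) and at 4213 ± 645 and 3976 ± 359 (fold 0.949, 0.846 to 1.06; exact permutation p = 0.563). The GENCODE span of Agrp overlaps other genes on both strands, Ctcf among them. Hcrt, the orexin gene, was at 8989 ± 831 and 10200 ± 1109 (fold 1.13, 1.025 to 1.253), and Trh, the thyrotropin-releasing hormone gene, at 3197 ± 361 and 2809 ± 333 (fold 0.879, 0.786 to 0.983), each with an adjusted p of 0.318 over the peptides. Without Ins2 replicate 4, Hcrt (log2 fold change 0.24) and Trh (-0.25) passed adjusted over the list alone (0.0292 each). As lists, the arcuate and orexigenic peptides (median log2 fold change -0.08, camera adjusted p = 0.522) and the anorexigenic peptides (-0.14, 0.162) were not called.

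**Figure D4:**
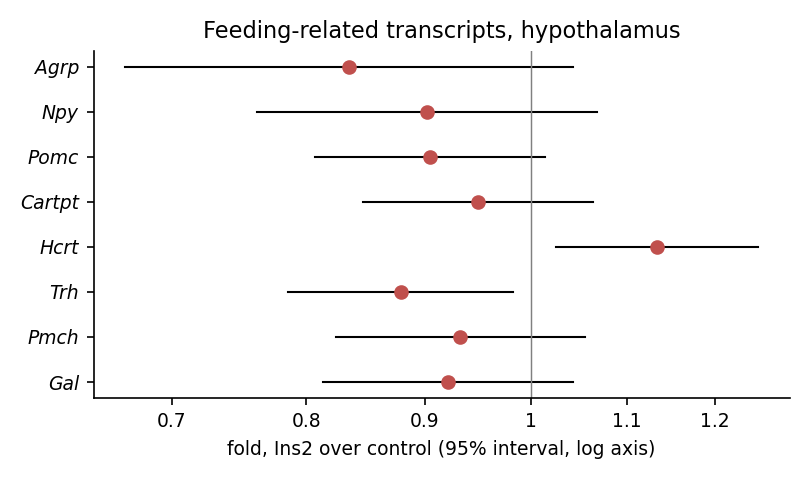
Fold of Ins2 over control hypothalamus for 8 feeding-related transcripts on a log axis, with points for the limma estimate and lines for its 95% interval (5 libraries per group). The intervals of Agrp, Npy, Pomc and Cartpt all include 1, and those of Hcrt (1.025 to 1.253) and Trh (0.786 to 0.983) do not.

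Of 47 gene lists tested in hypothalamus camera called 10, 5 upward and 5 downward. 0 were called with an estimated correlation (smallest adjusted p = 0.612, with 2 unadjusted p under 0.05) and 0 by fry, and list scores per library gave 4 lists with an unadjusted exact permutation p under 0.05 and 0 adjusted. The 37 uncalled lists had camera adjusted p-values from 0.0648 (nuclear genes of oxidative phosphorylation) to 0.913 (immediate early genes). Among their members Klf9 of the FOXO list (fold 1.15), Grin2b of the glutamate and GABA receptors (1.16), the endothelial transporter gene Slco1a4 (0.842) and Ddn, C1ql3 and Dsp of the cortex and hippocampus list (1.14, 1.17 and 0.572) passed adjusted over the list alone, though 64.2% of the exon bases of C1ql3 lie in genes of the opposite strand. The oxidative phosphorylation median of -0.03 was -0.07 (adjusted p = 7.52e-06) without control 2 and turned to 0.0242 (0.0381) without control 4. Lists of neuron, thalamus and oligodendrocyte precursor genes shifted upward. Other lists of neuronal genes did not. Glutamate and GABA receptors had a median log2 fold change of -0.04 (camera adjusted p = 0.598), and medians of the peptide and hormone lists were also below 0. Of 26 neuron genes 21 were above 0 (median log2 fold change 0.05, camera adjusted p = 0.00173; adjusted p = 0.612 with an estimated correlation), with Snap25 and Syp at folds of 0.977 and 1.04. Adjusted over the list alone Rbfox3 (fold 1.13) and the glutamate transporter gene Slc17a7 (36.1 ± 9.37 and 89.7 ± 34.8, fold 2.28) passed. Their median was 0.03 without control 1. Of 14 thalamus genes 11 were above 0 (median 0.17, camera adjusted p = 0.00173; adjusted p = 0.612 with an estimated correlation), with Slc17a6, Calb2 and Ntng1 at folds of 1.07, 0.969 and 1.105, and Gbx2 (fold 1.97), Synpo2 (1.37), Prkcd (1.22) and Rora (1.12) passed adjusted over the list alone. Markers of the neighbouring thalamus thus moved with those of neurons. Oligodendrocyte precursor genes (12 tested, median 0.08, camera adjusted p = 0.0161; adjusted p = 0.612 with an estimated correlation) included Cspg5, Ptprz1 and Bcas1 at folds of 1.05, 1.02 and 0.983 and Olig2, which passed adjusted over the list alone, at 1.16. This call was lost without control 1 (median 0.04, adjusted p = 0.111) or control 3 (0.08, 0.052).

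The ribosomal protein, ventricular and interferon lists shifted downward in hypothalamus. Of 76 ribosomal protein genes 60 were below 0 (median log2 fold change -0.07, camera adjusted p = 6.25e-06; adjusted p = 0.707 with an estimated correlation), with Rpl3, Rpl4 and Rpsa at folds of 0.936, 0.949 and 0.909 and 0 passing adjusted over the list alone. Control 4 had the highest score, 0.30 against -0.19 to 0.03 in the other libraries, and without it the median turned to 0.0153 (adjusted p = 0.963), while it was -0.11 without control 2 and -0.04 (0.00497) with the length trend of each library removed. Ependymal and cilia genes (26 tested, median -0.09, camera adjusted p = 0.00278; adjusted p = 0.612 with an estimated correlation) included S100b and Pltp at folds of 0.946 and 0.93. Cfap44 (0.762), Tekt1 (0.778) and Ccdc39 (0.841), genes of motile cilia, passed adjusted over the list alone. Tanycyte genes (17 tested, median -0.15, camera adjusted p = 0.00278; adjusted p = 0.612 with an estimated correlation), of the cells lining the floor of the ventricle, included Ptn, Col25a1 and Vim at folds of 0.969, 0.891 and 0.95 and Fndc3c1, which passed adjusted over the list alone, at 0.464. The ependymal call was lost without Ins2 replicate 4 (median -0.05, adjusted p = 0.0918) or control 3 (-0.08, 0.0877), and the tanycyte median was -0.06 without Ins2 replicate 4. Interferon-stimulated genes (39 tested, median -0.12, camera adjusted p = 0.00974; adjusted p = 0.612 with an estimated correlation), among them Cmpk2 and Stat2 at folds of 1.02 and 0.9753, lost their call without control 4 (median -0.08, adjusted p = 0.138).

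The remaining 3 called lists of the hypothalamus lost their call when any of several single libraries was left out, which also leaves fewer samples. Insulin signalling genes (36 tested, 25 above 0, median 0.04, camera adjusted p = 0.0299; adjusted p = 0.612 with an estimated correlation) had Grb10 and Akt1 at folds of 0.978 and 1.065. The call was lost without Ins2 replicates 3 or 5 or controls 3 or 4 (medians 0.03, 0.04, 0.05 and 0.02, adjusted p = 0.0523 to 0.138) and with equal totals per library (0.02, 0.0543) or the length trend removed (0.03, 0.0887). The median was 0.02 with the GC trend removed. Other hypothalamic hormone genes (16 tested, median -0.11, camera adjusted p = 0.044; adjusted p = 0.612 with an estimated correlation) had Avp, Sst and Oxt at folds of 0.998, 0.939 and 0.878. They lost their call without Ins2 replicates 3 or 5 or controls 1, 3 or 4 (medians -0.09, -0.07, -0.10, -0.08 and -0.07, adjusted p = 0.0548 to 0.152). This call was also lost with equal totals per library (-0.13, 0.0543), a mean of at least 50 (-0.10, 0.145) or the length trend removed (-0.08, 0.186). Fibroblast and meningeal genes (21 tested, median 0.15, camera adjusted p = 0.0453; adjusted p = 0.792 with an estimated correlation), with Vtn, Pdgfra and Fn1 at folds of 1.03, 1.06 and 1.11, had scores of 1.01 in Ins2 replicate 1 and 0.60 in Ins2 replicate 5 and at most 0.06 in the other 8 libraries. Their median was 0.00459 (0.753) without Ins2 replicate 1, 0.09 (0.452) without Ins2 replicate 5, 0.24 without Ins2 replicate 3 and 0.25 without Ins2 replicate 4. The call was also lost without controls 1, 2, 3 or 6 (medians 0.15, 0.18, 0.17 and 0.17, adjusted p = 0.0575 to 0.121). It was lost as well with a mean of at least 50 (0.15, 0.065) or with the GC trend (0.12, 0.0576) or length trend removed (0.14, 0.0719).

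Whether the tissues responded differently was tested over 13997 genes measured in both. The difference of the log2 fold changes passed for 15 genes, and 1484 had an unadjusted p under 0.05. Across genes, which are not independent replicates, the fold changes of the tissues had a Spearman rho of -0.14 and a Pearson r of -0.06. Jchain (4.09 in choroid plexus and 0.18 in hypothalamus, limma-based adjusted p = 0.0194) and Kcnq1ot1 (0.57 and -0.25, adjusted p = 0.0224) were higher in choroid plexus relative to hypothalamus. The other 13 were lower, led by Map1a (-0.36 and 0.18, adjusted p = 0.00174), Jade2 (-0.24 and 0.23), the EGF-domain protein gene Megf9 (-0.35 and 0.32), Nacc2 (-0.17 and 0.20), the spectrin gene Sptb (-0.18 and 0.25; these 4 at 0.0224) and the integrin gene Itga3 (-0.21 and 0.21, adjusted p = 0.0315). Among the remaining 7 were Fat1 and the clustered protocadherins Pcdhgb6 and Pcdhgc3, whose transcripts share exons. Only Map1a and Jchain were called whichever of the 21 libraries was left out, and the count ran from 2 to 44. With the length trend of each library removed it was 6, all among the 15, and the differences of the other 9 were -0.28 to -0.55 (adjusted p = 0.0597 to 0.127). It was 26 without choroid plexus Ins2 replicate 2, 29 without Ins2 replicate 4, 6 without Ins2 replicate 6, and 25, 2 and 7 without choroid plexus controls 1, 3 and 4. It was 3, 2, 3 and 2 without hypothalamus Ins2 replicates 2 to 5, and 4, 8 and 44 without hypothalamus controls 1, 4 and 6.

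**Figure D5:**
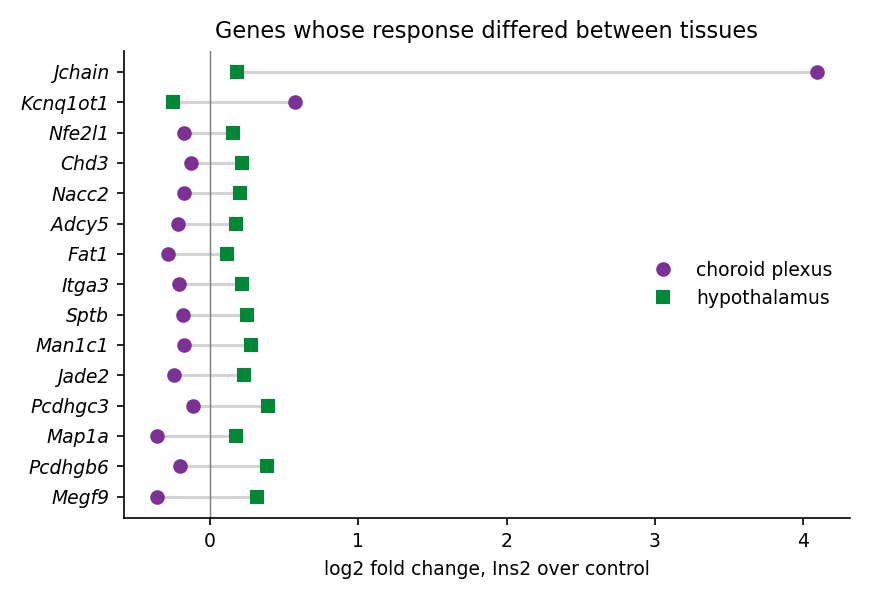
Log2 fold change of Ins2 over control in choroid plexus (purple circles) and hypothalamus (green squares) for the 15 genes whose response differed between the tissues, joined by grey lines. Jchain stands at 4.09 in choroid plexus and 0.18 in hypothalamus, and the 13 genes below Kcnq1ot1 are negative in choroid plexus and positive in hypothalamus.

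None of 35 lists differed in score change between the tissues after adjustment (100000 permutations). The smallest p-value was that of insulin signalling, whose mean score change was -0.04 in choroid plexus and 0.07 in hypothalamus (permutation p = 0.00243, adjusted p = 0.0851). Peptide hormone processing and beta cell genes changed by -0.36 and 0.10 (permutation p = 0.0184, adjusted p = 0.202). Interferon-stimulated genes changed by 0.35 and -0.15 (permutation p = 0.0216, adjusted p = 0.202) and MHC class I genes by 0.26 and -0.10 (permutation p = 0.0231, adjusted p = 0.202).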

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

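The tests of control 5 and of the macrophage score on the immune lists, of control 2 on the astrocyte list, of GC and length trends removed in both tissues, and the count of splits for hypothalamus genes were chosen only after the results were seen. In each group of samples, single libraries, gene values and list scores were searched for 1 sample far from the others. Of 126 groups searched, 6 had such a sample, and chance gives about 6. In Ins2 choroid plexus, replicate 4 had 2.90% of its reads in Rn45s against 1.775% to 2.175% in the others. In control choroid plexus, Dancr was at 96.7 in control 3 against 65.4 to 71.2, and the peptide hormone processing score of control 2 was 0.68 against -0.32 to -0.06. In hypothalamus, Ins2 replicate 2 held 62.1 M reads against 31.1 to 36.2 M, the interferon score of Ins2 replicate 1 was 0.10 against -0.23 to -0.16, and the neuron score of control 6 was 0.074 against -0.03 to -0.004.

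A difference between the tissues in their response to Ins2 singled out 15 genes. The choroid plexus response minus the hypothalamus response was 3.91 for Jchain and 0.82 for Kcnq1ot1 on the log2 scale. It was -0.54 for Map1a, -0.47 for Jade2, -0.67 for Megf9, -0.37 for Nacc2, -0.43 for Sptb, -0.42 for Itga3, -0.39 for Adcy5, -0.40 for Fat1, -0.59 for Pcdhgb6, -0.33 for Nfe2l1, -0.45 for Man1c1, -0.51 for Pcdhgc3 and -0.34 for Chd3, with standard errors from 0.07 to 0.13. Of 100 splits of the samples within each tissue, the real one included, only the real one gave as many as 15 genes, and the highest count in any other was 2. The count is therefore larger than in the other splits drawn. Which genes pass depended on single libraries, and with the length trend of each library removed 6 of the 15 were left (2 higher, 4 lower in choroid plexus relative to hypothalamus). Log2 fold changes in choroid plexus went with transcript length (Spearman rho -0.23), but the other 9 kept 80.3% to 94.4% of their difference with the trend removed (adjusted p = 0.0597 to 0.127). A length trend is thus argued against as the whole source of these 9, whose calls ended on slightly smaller differences, and stays open for a small part of them.

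Counts of calls within each tissue were set against splits in the same way, with the real one among the 100 in each count. In choroid plexus 2 of 100 splits gave at least 2 genes, with 4 the most in any other split, so random groupings seldom gave as many genes. The 14 gene lists called by camera were matched by 35 of 100 splits, and the other splits had a median of 12 lists and a highest count of 21. In hypothalamus the count of 0 genes cannot be tested this way, since all 100 splits give at least 0 (the highest in any other was 1). The 10 lists there were matched by 38 of 100 splits, with a median of 8 and a highest count of 21. The numbers of lists called in both tissues are thus no larger than random groupings of the same samples gave, and no single list can be taken as an effect of Ins2 from its camera p-value alone.

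The first pattern weighed is the upward shift of immune lists in Ins2 choroid plexus. Ins2 replicates 4 and 5 did not share it for 3 lists, where their scores lay within the control range. These were MHC class I (-0.12 and -0.004), interferon-stimulated (-0.08 and -0.12) and MHC class II genes (-0.05 and 0.06). Of the Ins2 libraries, replicate 5 had the highest Ins2 value (1041) and replicate 4 the lowest (598). MHC class I, interferon-stimulated and T and NK cell genes had medians of 0.18, 0.18 and 0.70 without control 5, against 0.21, 0.25 and 0.91 with it. All 3 lists stayed called. Their shift thus did not rest on control 5 alone. With the macrophage score as a covariate all 3 lists stayed called as well (medians 0.16, 0.17 and 0.53). Part of the shift thus remained beyond that score, which is only an indirect measure of macrophages. With the length trend removed the medians of those 3 lists and MHC class II were little changed (0.20, 0.24, 0.89 and 0.69). That argues against a length trend as their whole source. All 4 lists also stayed called with the GC trend removed, but fold changes hardly went with GC here (Spearman rho -0.05), so this tests little. Camera called as many lists in 35 of 100 splits, so the kept calls by themselves decide nothing. For MHC class II neither control 5 nor macrophages can be told apart from an effect of Ins2, because the median of 0.71 fell to 0.29 without control 5 and to 0.26 with the covariate while the call was kept. A random difference between the groups stays open for all 4 lists, as does a response to Ins2 or to the way it was introduced, which the design does not separate.

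The second pattern is the lower astrocyte list in Ins2 choroid plexus. Adjoining brain tissue in control 2 could account for part of it, since the median of -0.31 was -0.10 without control 2 (adjusted p = 0.0229). The call was kept on this smaller shift, and with controls 2 and 5 both left out the median was -0.21 (adjusted p = 0.0002365). Both of these fits keep control 1, which also had a high astrocyte score (0.24), with Gfap at 453 and Aqp4 at 238. Controls 3, 4 and 5 scored -0.26, -0.38 and -0.56, within the range of the Ins2 libraries (-0.69 to -0.24). The lower list thus rested on controls 1 and 2, and leaving out both together was not tested. For the part lost with control 2, adjoining tissue cannot be told apart from other differences of that library, since leaving it out removes them all. The myelin list turned from -0.21 to 0.28 without the same library and was -0.59 without control 5. A random difference between the groups and an effect of Ins2 on glial transcripts also stay open.

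The third pattern is the lower ribosomal protein list and the higher neuron list in Ins2 hypothalamus. Library GC slopes, measured as the Spearman correlation of each gene's deviation with its GC content, averaged 0.17 in Ins2 and -0.09 in control libraries, a difference of 0.26 that other splits reached by chance (exact permutation p = 0.119). The GC trend as the whole source is argued against, because the medians of both lists (2 of 2) were little changed with it removed (-0.07 and 0.06). Both calls were also kept, which by itself decides nothing, since 38 of 100 splits gave as many lists. With the length trend removed the neuron median was 0.05, while that of ribosomal proteins fell from -0.07 to -0.04 (adjusted p = 0.00497), so a length trend stays open for part of the ribosomal shift. The ribosomal protein list also rested on control 4, without which its median was 0.0153. A random difference between the groups, a different share of neurons or of adjoining thalamus in the dissected tissue and an effect of Ins2 stay open, and the last 2 were not tested.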

How the results depend on the processing

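Ins2 in choroid plexus kept its direction and its call under 27 alternatives, and was dropped where an absolute log2 fold change of at least 1 was asked for, since its own was 0.92. In hypothalamus all 5 Ins2 reads lay in Ins2 replicate 4, so the 12 alternatives there could not raise a call and test nothing further. Without that library every value was 0. Of single named genes in choroid plexus, 3344 results under alternatives kept their side of the threshold, 12 passed newly and 3 lost their call. In hypothalamus 3727 kept it and 14 passed newly. Of list results in choroid plexus, 752 kept their side, 51 passed newly and 67 lost their call in the same direction, and 2 were reversed. In hypothalamus these were 866, 20 and 48, with 3 reversed. The 2 edgeR scalings, TMM and DESeq2 size factors, gave the same counts of genes, 2 in choroid plexus and 0 in hypothalamus. Genes called in choroid plexus, 2 in the design used, were 1 with a mean of at least 50 (Ins2) and 1 with an absolute log2 fold change of at least 1 (Jchain), which keep fewer genes. They were 6 with array weights and 25 with DESeq2, and 1 to 4 when each library was left out. With no filter limma called Slfn1 (log2 fold change 3.06, adjusted p = 0.0113) beside Ins2 and Jchain. Genes called in hypothalamus were 39 with DESeq2 and 0 to 18 when each library was left out. Lists called fell from 14 and 10 to 0 in both tissues with an estimated correlation and to 0 with fry, and hypothalamus lists numbered 5 to 12 when each library was left out. Feeding peptides past the threshold were 0 to 2, and genes that differed between tissues 2 to 44, when each library was left out. The latter were 6 with each library's length trend removed, an alternative chosen after seeing the data. Direction was reversed for the myelin list of choroid plexus without controls 2 and 5 (0.24, chosen after seeing the data), and the circadian clock list turned there too, from 0.07 to -0.02. When each library was left out, medians of the myelin list ran from -0.59 to 0.28 (without control 2). In hypothalamus they ran from -0.108 to 0.0153 for ribosomal proteins, from -0.074 to 0.0242 for oxidative phosphorylation, each turning without control 4, and from 0.00459 (without Ins2 replicate 1) to 0.25 for fibroblasts. Apart from smaller numbers of genes or samples, the cause was not tested.

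The replicate block did not rest on a known pairing: correlations of same-numbered samples ran from -0.15 to 0.14 in choroid plexus, where 1 of 5 numbers fitted best with its own partner, and from -0.07 to 0.02 in hypothalamus, where none did. With the block by title number, 2 genes were called in choroid plexus, 57 in hypothalamus (Irs2 among them) and 36 for the difference between tissues. The lists were again 14 and 10, but not the same ones. In choroid plexus, T and NK cells and extracellular matrix were not called and cholesterol synthesis and myelin were, and in hypothalamus, fibroblasts were not called and MHC class I was. This block drops samples without a same-numbered partner: Ins2 replicate 6 in choroid plexus, and Ins2 replicate 5 and control 6 in hypothalamus. T and NK cells and extracellular matrix also lost their call without Ins2 replicate 6 alone (camera adjusted p = 0.0734 and 0.0753), so the block need not be the source. With the block by bracketed code, 6 genes and 2 feeding peptides, Hcrt and Trh, were called in hypothalamus. Depth limits weakly expressed genes, since a count of 0 allows up to 0.116 reads per M reads in the smallest library.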

Other observations

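The test of plasma cell genes beside Jchain was chosen only after the result for Jchain was seen. Jchain is made by plasma cells, so cells of that kind in the Ins2 choroid plexus were a candidate source of its rise. The summed values of 6 other plasma cell genes were 109 ± 32.8 in Ins2 and 83.9 ± 17.9 in control choroid plexus, a difference of 25.3 (exact permutation p = 0.167). Of these, Mzb1 was at 35.8 ± 11.9 and 22.8 ± 4.65 (exact permutation p = 0.0519, adjusted 0.312) and Irf4 at 8.47 ± 5.33 and 3.40 ± 1.70 (p = 0.0693, adjusted 0.312), while Derl3, Tnfrsf17, Pou2af1 and Eaf2 had adjusted p-values of 1. The transcripts are few, so the test leaves open whether plasma cells or another source raised Jchain. In hypothalamus Jchain was at 62.5 ± 15.9 and 71.1 ± 20.8.

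Transcript length and GC content went with the fold changes to different degrees in the tissues. In choroid plexus the Spearman correlation of log2 fold change with length was -0.23, with GC -0.05, and library slopes did not separate the groups (exact permutation p = 0.175 for length and 0.952 for GC). The 21 genes lower by DESeq2 in choroid plexus had a median length of 8161 bases against 3834 in all tested genes. In hypothalamus the correlation was 0.13 with length (exact permutation p = 0.468 for the slopes) and 0.37 with GC, and the 30 genes higher by DESeq2 had a median GC of 55.4% against 50% in all tested genes.

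The first principal component held 20.8% of the variance in choroid plexus, with controls 2 (-45.4) and 5 (38.7) farthest out, and 19.5% in hypothalamus, with control 4 (-50.7) farthest out.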
